A study of Mus musculus with 4 samples.

How the data were processed

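Gene expression was profiled in 4 samples of lineage-negative mouse bone marrow cells, 2 from floxed Atad3a controls and 2 from floxed Atad3a mice with Mx1Cre, all on day 12 after poly I:C. Per the labels' protocols, total RNA was amplified to biotin-labelled cRNA and hybridised to Illumina mouse WG-6 v2 bead arrays, 1 colour and 1 array per sample. Groups and replicate numbers were taken from the sample titles.

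The deposited scanner table gives, per the file headers, a non-normalized signal intensity for each of 45281 probes on each array, and beside it a detection p-value against the negative control beads. Per the submitters' processing notes the values came from GenomeStudio, whose version is not given in the sources used here, and neither are background subtraction and bead filters. The deposited series matrix holds the authors' processed intensity on a linear scale. Its columns had medians of 100.5, 100.5, 100.6 and 100.6, the same lowest and highest values (74.2 and 21732.2), and rank correlations of at least 0.999994 with the scanner signal of the same array, so it is quantile normalized by its values. The authors' method is not given in the sources used here. The matrix was used as an alternative only.

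Signals were background corrected with limma 3.58.1 in R 4.3.3 by the steps of neqc. These fit a normal plus exponential model to negative control beads, inferred here from the detection p-values, and add an offset of 16. The corrected intensities were then quantile normalized, and log2 was taken last. Probes with a detection p under 0.05 on at least 2 of the 4 arrays were kept, 18367 in all. Background correction and the offset set how large the change of a dim probe looks, and a threshold of detection leaves out genes near background. Probe genes came from the platform table where it lists 1 gene, updated through the Entrez ID: 34885 probes have 1 gene, of which 34807 matched the RefSeq table (assembly GRCm38.p6, used for names only), and 18 have several and were left unnamed. The array's own names in the scanner table named a further 2165 probes for genes without a platform-table probe, and 8213 stayed unnamed here. The platform annotation can be old, so some probes may carry an outdated gene. Where a gene had several detected probes, the one with the highest mean over the 4 arrays represented it, which gave 10519 genes. Of 1141 called genes with more than 1 detected probe, 12 had a called probe in the opposite direction.

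Groups were compared with limma's lmFit and eBayes (residual degrees of freedom 2, prior degrees of freedom 2.72), with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. Changes are given as deletion minus control, as fold or log2 change with the standard error (SE) of the log2 change. A probe not detected on either array of a group has only a bound there: the other group's mean was set against the mean of, per array, the higher of the lowest signal among detected probes and the probe's own, and the change is given as at least that many fold. There were 171 higher genes undetected in both controls and 207 lower genes undetected in both deletion samples. A gene is called undetected by its representing probe alone, and another of its probes may be detected. Gene lists, 36 in number, were written before the data were examined and cover cell types of bone marrow, possible contaminants, mitochondrial and stress pathways, interferon and cell cycle genes and sex-linked genes. Lists with at least 5 detected genes, 35 of them, were tested two-sided by camera with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. With the correlation estimated for each list none of the 21 calls held. That test has as few degrees of freedom as the arrays leave.

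The genes named were fixed by rule at the same time: Atad3a, the 10 largest rises and 10 largest falls among called genes whose groups do not overlap, up to 4 of the members that moved farthest in the direction of each called list, the 2 with the largest change in each other list where they pass, and a set of names that includes Pink1, Phb, Sqstm1, Kit, Ly6a, Cd34, Gata1, Klf1, Pax5, Mpo, Itga2b, Tfam, Hspd1, Ddit3, Isg15 and Cdkn1a. Others were chosen after their values were seen. A further 10 lists, among them plasma cell, endoplasmic reticulum chaperone, serine and one-carbon, aminoacyl-tRNA synthetase, erythroid regulator, red cell membrane and B cell stage genes, were chosen after the main results were seen and adjusted among themselves.

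Alternatives were no background correction, normexp without control probes at an offset of 50, median scaling, cyclic loess, no detection filter, detection p under 0.01 on all 4 arrays, an intensity trend with a robust prior, the replicate number as a block, the authors' processed values, each array left out in turn, the mean of all detected probes, a threshold of at least 2-fold, camera on ranks and camera with estimated correlation. Naming by the platform table alone was added after seeing the data. A slide block was not run because the files used give no slides.

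The steps were tested on simulated data, 2 against 2 arrays and 18396 probes. It was made from the real probe means, with spreads drawn at random from the fitted prior. Of 100 genes changed 4-fold, 52% were called in the right direction, with a median log2 size of 1.97. Of 100 changed 2-fold 0% were called, with a median of 0.92. Few genes were changed there, which makes the adjustment stricter than in the real data. Of 57 probes called, 5 were unchanged ones. A shifted list of 40 genes was called with the preset correlation (adjusted p = 4.59e-49) and missed with an estimated one (0.166), and 0 of 20 unshifted lists were called. Simulated genes varied independently of each other, while the estimated correlation of a real list was as high as 0.498 (T and NK cell genes). The simulated lists therefore cannot check the preset correlation for the real ones. The number of arrays limits the precision of every value.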

Results

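Gene expression was measured in lineage-negative bone marrow cells, the progenitor-rich fraction that remains when cells carrying mature blood cell antigens are removed, from mice with floxed Atad3a alleles. Atad3a encodes an ATPase anchored in the inner mitochondrial membrane. The deletion group also carried Mx1Cre, a Cre recombinase under an interferon-inducible promoter that is switched on with poly I:C, a synthetic RNA, and the control group did not. The question was which transcripts differ when Atad3a is deleted in these cells. Because only the deletion group carried Mx1Cre, effects of Cre itself and of Atad3a loss cannot be told apart here. Below, "after deletion" names the group and not a cause. All 4 samples, 2 controls and 2 deletions, were taken on day 12 after poly I:C, and each was hybridised to 1 mouse bead array with 45281 probes. Detected probes numbered 17536 and 16968 on the control arrays and 17901 and 18072 on the deletion arrays, which is 38.7%, 37.5%, 39.5% and 39.9% of all probes. Mean raw signals were 387, 419, 381 and 376 in the same order. The labels do not say whether the replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision, and relabelling 2 against 2 arrays cannot give a permutation p below 0.333. Slide, batch and scan date are not given in the sources used here.

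Atad3a mRNA was 2.10-fold lower in the deletion samples (log2 change -1.07, SE 0.13, adjusted p = 0.00866). Its log2 intensity was 10.99 ± 0.09 (SD, n = 2) in controls and 9.92 ± 0.12 (SD, n = 2) after deletion, and both deletion arrays lay below both control arrays. The transcript stayed detected on all 4 arrays. A single probe measures Atad3a, and its position relative to the deleted exons was not determined here; a probe outside them would check nothing about the labels. With deletion replicate 1 left out the log2 change was -1.14 and the adjusted p 0.0510, and without deletion replicate 2 they were -0.98 and 0.0667.

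Expression differed widely between the groups. Of 10519 named genes tested, each by its brightest detected probe, 1552 were higher and 1487 lower after Atad3a deletion at an adjusted p under 0.05, and 7480 did not pass. At least a 2-fold change was present in 561 of the higher and 621 of the lower genes. The 10 largest falls included the red cell genes Slc4a1, Ermap and Aqp1 and the early B cell gene Vpreb3, and the 10 largest rises included Trib3, Slc7a3, Chac1 and Nupr1 of the amino acid stress response. By probe, 2577 of 18367 were higher and 2382 lower. Arrays of 1 group correlated at 0.986 (controls) and 0.990 (deletion) across detected probes, and arrays of different groups at 0.923 to 0.942. The leading principal component separated the groups and held 84% of the variance. The counts depended on single arrays: 1311 higher and 1359 lower without control replicate 1, 926 and 932 without control replicate 2, 346 and 464 without deletion replicate 1, and 278 and 419 without deletion replicate 2. Of 126 named genes other than Atad3a, 45 lost their calls without deletion replicate 2, 42 without deletion replicate 1, 16 without control replicate 2 and 11 without control replicate 1. Without background correction 45 of the 126 had changes smaller by over 1.5-fold. Median scaling in place of quantile normalization gave 1223 higher and 1854 lower genes, so that 39.8% of the calls were higher against 51.1%, with the median of all genes at -0.10 on the log2 scale.

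**Figure D1:**
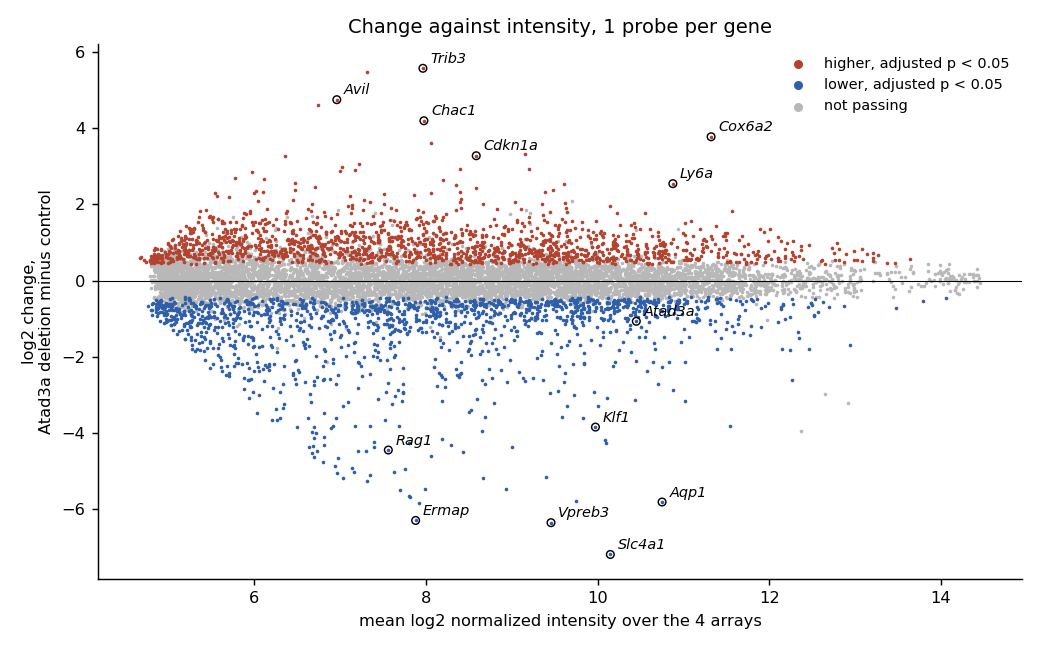
Log2 change between deletion and control (vertical axis) against the mean log2 normalized intensity over the 4 arrays (horizontal axis) for the brightest detected probe of each of the 10519 genes. Red and blue points are the 1552 higher and 1487 lower genes at an adjusted p under 0.05, grey points did not pass, and circles mark named genes from Trib3 at 5.57 to Slc4a1 at -7.19.

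Targets of the integrated stress response, the program run by the transcription factor ATF4, rose together and held several of the largest changes on the array. Trib3, a pseudokinase induced by ATF4, rose 47.5-fold (log2 change 5.57, SE 0.16). By its brightest probe Slc7a3, a cationic amino acid transporter, was not detected on either control array and rose at least 32.3-fold (adjusted p = 0.000859). Chac1, which breaks down glutathione, rose 18.3-fold (SE 0.21 on the log2 scale), and Nupr1, a stress-induced nuclear protein, 12.2-fold (SE 0.14). Of 44 tested members 32 rose and 1 fell, against 36 and 1 adjusted over the list alone, with a median log2 change of 1.30. The list was called by limma's camera test (adjusted p = 7.54e-14 with the preset correlation, adjusted p = 0.324 with an estimated correlation). The member that fell was Ppp1r15a, the phosphatase subunit that reverses the signal to ATF4 (log2 change -1.63, SE 0.12). Ddit3, which encodes CHOP, rose 2.70-fold (SE 0.11). With the 6 members that were undetected in a group set at their bound, the median was 1.17, and it was 0.70 both without a detection filter and with detection at p under 0.01 on all arrays. The members that rose numbered 21 without deletion replicate 1 or deletion replicate 2. In the same arrays the erythroid list had a median log2 change of -2.66 and the B lymphoid list -2.24. With the mean of all detected probes of a gene in place of the brightest, the log2 change was 3.42 for Trib3 and 2.61 for Slc7a3, whose dimmer probe had a log2 change of -0.24 (adjusted p = 0.257).

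The other genes among the 10 largest rises are given next, and whether they belong to the same response was not tested. Avil, an actin-binding protein, was not detected on the control arrays and rose at least 19.8-fold (adjusted p = 0.000859), and Aldh1l2, the mitochondrial formyltetrahydrofolate dehydrogenase, likewise rose at least 16.1-fold (adjusted p = 0.0014). Cox6a2, the heart and muscle isoform of a cytochrome c oxidase subunit, rose 13.7-fold (log2 change 3.77, SE 0.12). Atf5, a transcription factor of the mitochondrial stress response, rose by a log2 change of 3.32 (SE 0.25). Cdkn1a, the cell cycle inhibitor p21, rose 9.69-fold (SE 0.20), and Ifi205, an interferon-induced gene without detection in controls, at least 7.76-fold (adjusted p = 0.00235). The mean of all detected probes gave smaller log2 changes of 3.30 for Aldh1l2, 2.67 for Cdkn1a and 2.05 for Ifi205.

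Genes of red cell precursors fell more than those of any other list. Slc4a1, the band 3 anion exchanger, was 146-fold lower (log2 change -7.19, SE 1.42), Ermap, an erythroid membrane protein, 78.6-fold lower (SE 0.25), Trim10, a factor of late erythroid maturation, 57.0-fold lower (SE 0.44), and Aqp1, the red cell water channel, 56.2-fold lower (SE 0.62). The erythroid transcription factors Klf1 and Gata1 were 14.4-fold (SE 0.34) and 4.39-fold (SE 0.14) lower. Of 36 tested erythroid genes 34 fell and 0 rose, against 35 and 0 adjusted over the list alone, with a median log2 change of -2.66 (camera adjusted p = 6.85e-19, adjusted p = 0.324 with an estimated correlation). Genes of heme synthesis and iron handling fell with them: 25 of 31 fell and 0 rose, against 25 and 1 adjusted over the list alone, with a median of -1.38 (adjusted p = 1.40e-10, adjusted p = 0.324 with an estimated correlation). Alas2, the erythroid enzyme of the rate-limiting step of heme synthesis, was 44.6-fold lower (SE 0.58), Abcb6, a porphyrin transporter, 7.39-fold (SE 0.20), Uros, uroporphyrinogen III synthase, 6.23-fold (SE 0.15), and Fech, ferrochelatase, 5.34-fold (SE 0.21). Further genes among the 10 largest falls were the glutamine transporter Slc38a5 (54.8-fold, SE 0.57), Nxpe2 (51.1-fold, SE 0.41), the red cell membrane skeleton gene Dmtn (50.1-fold, SE 0.26) and the sterol transporter Abcg4 (44.9-fold, SE 0.26). Without deletion replicate 1 and without deletion replicate 2 the log2 changes were -6.37 and -4.64 for Alas2, -6.74 and -4.87 for Aqp1, -6.68 and -4.93 for Slc38a5, and -6.52 and -5.21 for Trim10, and that of Nxpe2 was -6.30 without deletion replicate 1. Without deletion replicate 2, 15 heme and iron genes fell. Each of Slc4a1, Ermap, Trim10, Alas2, Nxpe2, Dmtn and Abcg4 was detected on 1 of the 2 deletion arrays, and with each deletion array at its floor or above their falls were 120-fold, 65.9-fold, 46.3-fold, 36.8-fold, 42.1-fold, 44.8-fold and 39.9-fold in that order. Slc4a1 read 8.73 and 4.38 on these arrays, and its log2 change was -5.01 without deletion replicate 2 and -9.36 without deletion replicate 1; its call was lost without either control array (adjusted p = 0.0775 and 0.0924), without a detection filter (0.0605) and with an intensity trend and robust prior (0.131). The erythroid medians were -2.49 on deletion replicate 1 and -2.96 on deletion replicate 2, relative to the control mean, and 29 of the 36 members were lower on the latter. The median over all 4 arrays was -1.95 without background correction, and the authors' processed values also gave a smaller fall by over 1.5-fold. Over all detected probes the log2 change was -1.44 for Fech, -1.69 for Uros, -4.14 for Nxpe2 and -4.77 for Trim10.

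Early B lineage genes fell as well. Vpreb3, an early B cell gene, was 81.8-fold lower (log2 change -6.35, SE 0.33), the recombinase gene Rag1 21.8-fold lower (SE 0.25) and Fcrla 19.2-fold lower (SE 0.24). Of 29 tested B lymphoid genes 20 fell and 2 rose, both over all probes and adjusted over the list alone, and the median log2 change was -2.24, or -1.86 with 4 undetected members at their bound (camera adjusted p = 6.44e-08, adjusted p = 0.324 with an estimated correlation). The members that rose, chosen after their values were seen, were Dntt, the template-independent DNA polymerase of early lymphoid progenitors (log2 change 2.31, SE 0.15), and Cd180 (0.55). Only 1 member rose with the replicate block, and likewise with the mean of all detected probes. The B lymphoid median depended on dim probes: it was -0.95 without background correction, -1.26 with normexp without control probes, -0.93 with the authors' processed values and -1.16 without a detection filter.

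T and NK cell genes moved the opposite way from B cell genes. Cd247, the zeta chain of the T cell receptor complex, was 3.99-fold higher (SE 0.29), Gata3 2.67-fold (SE 0.19), Cd3g 2.57-fold (SE 0.13) and Cd8b1 2.56-fold (SE 0.21). Of 27 tested members 17 rose and 0 fell, against 20 and 0 adjusted over the list alone, with a median log2 change of 0.88 (adjusted p = 1.25e-06, adjusted p = 0.353 with an estimated correlation). The deletion arrays differed here, with medians of 1.03 on replicate 1 and 0.73 on replicate 2, and 26 of 27 members were lower on the latter. Without control replicate 2, deletion replicate 1 or deletion replicate 2, 10, 2 and 5 members rose. The calls on Cd247 (adjusted p = 0.0739 and 0.0581 without deletion replicate 1 and 2) and Cd8b1 (0.0535 without control replicate 2 and 0.0657 without deletion replicate 1) were lost. The log2 change of Cd247 over the mean of its detected probes was 1.07.

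Stem and early progenitor genes were mostly higher. Ly6a, which encodes the stem cell antigen Sca-1 and is also interferon-inducible, rose 5.83-fold (log2 change 2.54, SE 0.12). Hoxa7 rose 2.95-fold (SE 0.16), the stem cell niche ligand gene Angpt1, undetected in controls, at least 2.59-fold (adjusted p = 0.00544) and Cd34 2.06-fold (SE 0.16). Of 31 members 16 rose and 3 fell, against 21 and 6 adjusted over the list alone, with a median of 0.77 (adjusted p = 0.000596, adjusted p = 0.324 with an estimated correlation). The 3 that fell were Kit, the stem cell factor receptor (log2 change -0.82, SE 0.18), and, chosen after their values were seen, Mllt3 (-1.24) and Eng (-1.22). A dimmer Kit probe had a log2 change of 0.44 (adjusted p = 0.386), the mean of both was -0.19 (adjusted p = 0.505), and the call on Kit was lost without any 1 of the 4 arrays. The same call was lost with the replicate block (adjusted p = 0.0501) and without a detection filter (0.0593). Without deletion replicate 1 or deletion replicate 2, 5 and 2 list members rose and 1 and 0 fell. The call on Cd34 was lost without control replicate 2 or deletion replicate 2 (adjusted p = 0.0585 and 0.0777) and that on Hoxa7 without deletion replicate 2 (0.0502).

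Megakaryocyte and platelet genes rose as a group. Ppbp, a platelet chemokine, was 4.74-fold higher (SE 0.35), Treml1 3.64-fold (SE 0.24), the platelet receptor subunit Gp1bb, undetected in controls, at least 2.55-fold (adjusted p = 0.0309), Pf4 2.58-fold (SE 0.23) and Itga2b, the integrin CD41, 2.36-fold (SE 0.25). Of 21 members 13 rose and 1 fell, against 16 and 1 adjusted over the list alone, with a median of 1.09 (adjusted p = 3.40e-05, adjusted p = 0.324 with an estimated correlation). The gene that fell, chosen after its value was seen, was Gp9 (-0.90). Without deletion replicate 1 or deletion replicate 2, 6 and 2 members rose, and none fell without any 1 of the 4 arrays. Calls were lost without control replicate 1 for Ppbp and Gp1bb (adjusted p = 0.0540 and 0.0921), without control replicate 2 for the same genes (0.0604 and 0.0633), without deletion replicate 1 for Pf4 and Itga2b (0.0708 and 0.104), and without deletion replicate 2 for Pf4, Itga2b and Gp1bb (0.0990, 0.138 and 0.0909). The calls on Gp1bb and Itga2b also ended without a detection filter (0.0654 and 0.0574).

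Among myeloid genes, 20 of 43 monocyte, macrophage and dendritic cell markers rose and 1 fell, against 20 and 2 adjusted over the list alone (median 0.40, adjusted p = 0.000382, adjusted p = 0.324 with an estimated correlation). Bst2, also interferon-inducible, rose 3.65-fold (SE 0.28), the class II antigen gene H2-Eb1 3.32-fold (SE 0.17), the chemokine gene Ccl6 3.09-fold (SE 0.12) and Siglech, a plasmacytoid dendritic cell marker, 2.98-fold (SE 0.13). The gene that fell, chosen after its value was seen, was the iron exporter Slc40a1 (-1.82), and 9 and 8 members rose without deletion replicate 1 or 2. Of 26 eosinophil, basophil and mast cell genes 13 rose and 4 fell, against 15 and 7 adjusted over the list alone (median 0.68, adjusted p = 0.0316, adjusted p = 0.353 with an estimated correlation). The IgE receptor chains Ms4a2 and Fcer1a rose 3.62-fold (SE 0.16) and 3.54-fold (SE 0.14) and Ccl3 3.05-fold (SE 0.14). The 4 that fell, chosen after their values were seen, were the eosinophil granule genes Epx (-2.08), Ear2 (-1.34) and Ear3 (-1.22), and Il1rl1 (-0.78). Cma1, a mast cell protease gene undetected in controls, was at least 2.94-fold higher without passing (adjusted p = 0.119). It read 7.55 and 5.63 on the deletion arrays, and it passed without deletion replicate 2 (adjusted p = 0.0175) but not without deletion replicate 1 (adjusted p = 0.111). The call on Bst2 was lost without control replicate 2 (adjusted p = 0.0582). The call on the eosinophil, basophil and mast cell list was lost without the same array (adjusted p = 0.0583), and 6 and 5 members rose without deletion replicate 1 or 2, with 5 and 2 falls. Neither neutrophil list passed. In the primary granule list 7 of 21 rose and 8 fell, against 10 and 8 adjusted over the list alone (adjusted p = 0.676), with neutrophil elastase, Elane, 8.73-fold lower (SE 0.28) and Cebpa, detected on 1 control array, 2.55-fold higher (SE 0.29), or 2.17-fold with each control array at its floor or above. The call on Cebpa was lost without a detection filter (adjusted p = 0.0666), deletion replicate 1 (0.100) or deletion replicate 2 (0.145). Mpo had a log2 change of 0.04 (SE 0.11, adjusted p = 0.812), and its 3 dimmer probes had changes of -0.35 to -0.70 that did not pass, with -0.40 for the mean of all 4 (adjusted p = 0.0949). In the mature neutrophil list 8 of 24 rose and 1 fell, against 9 and 2 adjusted over the list alone (adjusted p = 0.144), with Lcn2 3.49-fold higher (SE 0.18) and Tnfaip2 3.83-fold lower (SE 0.13). Without control replicate 2, deletion replicate 1 or deletion replicate 2, 5, 0 and 1 primary granule genes rose and 4, 1 and 1 fell, while 5, 3 and 2 mature neutrophil genes rose and 1, 2 and 1 fell.

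Stroma and endothelium markers, which a lineage-negative fraction can hold, were also higher in part. Col4a1, a basement membrane collagen, rose 7.33-fold (SE 0.12), Stab2 2.60-fold (SE 0.32), the adipocyte hormone gene Adipoq 2.59-fold (SE 0.11) and Bgn 2.52-fold (SE 0.28). Of 26 members 12 rose and 4 fell, against 14 and 4 adjusted over the list alone, with a median of 0.45, or 0.24 with 4 undetected members at their bound (adjusted p = 0.0149, adjusted p = 0.324 with an estimated correlation). The 4 that fell, chosen after their values were seen, were Fn1 (-0.95), Selenop (-0.87), Ibsp (-0.66) and Plvap (-0.62). Without control replicate 2, deletion replicate 1 or deletion replicate 2, 4, 2 and 3 members rose and 2, 0 and 0 fell, and without control replicate 1 2 fell. The log2 change of Stab2 was 0.54 without background correction (adjusted p = 0.0538) and 0.50 with the authors' processed values (adjusted p = 0.0623), and its call was also lost without a detection filter (0.0812), control replicate 1 (0.111), control replicate 2 (0.100) or deletion replicate 1 (0.0749). The call on Bgn was lost without a detection filter (0.0597), control replicate 2 (0.0972), deletion replicate 1 (0.100) or deletion replicate 2 (0.0505). The call was lost when detection at p under 0.01 on all arrays was required (adjusted p = 0.0823).

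**Figure D2:**
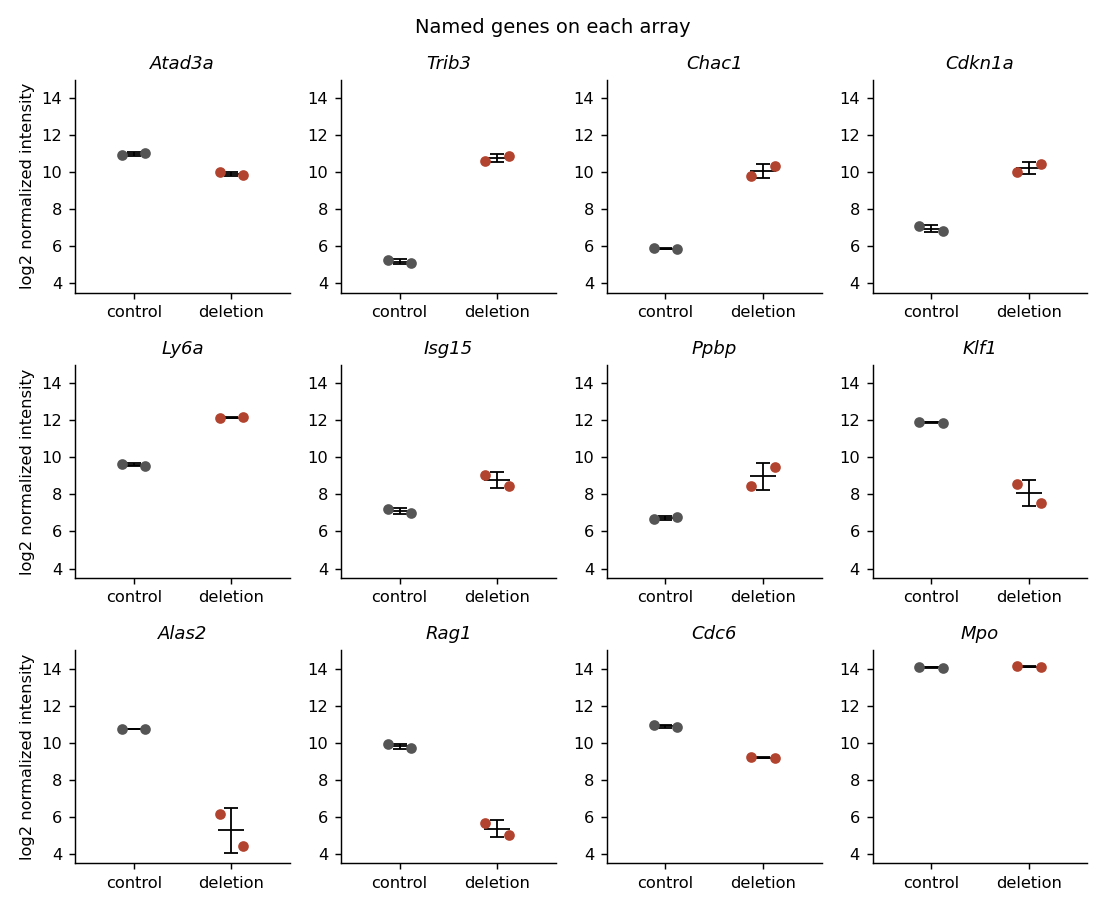
Log2 normalized intensity (vertical axis) of 12 named genes on each array, with points for the 2 control and 2 deletion arrays, a short line for the group mean and bars for the SD. Alas2 fell from 10.73 to 5.26 with deletion arrays at 6.12 and 4.39, while Mpo read 14.06 in controls and 14.10 after deletion.

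Interferon response genes were higher in the deletion samples, although both groups had received poly I:C on the same schedule. Beside Ly6a and Ifi205, the antiviral genes Oas1g and Ifit3 rose 5.67-fold (SE 0.14) and 3.72-fold (SE 0.30), and the ubiquitin-like modifier Isg15 3.19-fold (SE 0.24). Of 51 members 38 rose and 0 fell, against 41 and 1 adjusted over the list alone, with a median of 0.98 (adjusted p = 2.93e-11, adjusted p = 0.324 with an estimated correlation). Medians were 1.13 on deletion replicate 1 and 0.87 on deletion replicate 2, and 11 and 15 members rose without deletion replicate 1 or 2, with 1 and 0 falls. The call on Ifit3 was lost without control replicate 1 (adjusted p = 0.0532) and that on Isg15 without control replicate 2 (0.0565). In these arrays the T and NK cell list, with a median of 0.88, and the monocyte and dendritic cell list, with 0.40, moved the same way, and the erythroid and B lymphoid lists fell with medians of -2.66 and -2.24. Inflammatory cytokine and NF-kB target genes rose less evenly, 11 of 27 up and 4 down, against 12 and 4 adjusted over the list alone (median 0.44, adjusted p = 0.0369, adjusted p = 0.324 with an estimated correlation). Beside Ccl3, Ccl4 rose 2.49-fold (SE 0.17), Tnf 2.48-fold (SE 0.20) and Csf1 2.41-fold (SE 0.16). Of the 4 that fell, Tnfaip2 is given above, and Cd40 (-2.70), Birc3 (-0.66) and Il18 (-0.53) were chosen after their values were seen. The call was lost without control replicate 1 (adjusted p = 0.0762) or deletion replicate 1 (adjusted p = 0.0701). Without deletion replicate 1 or 2, 2 and 3 members rose, and 2 fell without any 1 of the 4 arrays. Calls were lost on Tnf (adjusted p = 0.0747 and 0.0535 without deletion replicate 1 and 2), Ccl4 (0.0532 without deletion replicate 1) and Csf1 (0.0574 without deletion replicate 2).

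Cell cycle genes were lower. Among DNA replication and G1/S genes E2f2 was 4.39-fold lower (SE 0.17), Ccne1, which encodes cyclin E1, 4.04-fold (SE 0.22), Orc1 3.93-fold (SE 0.31) and the replication licensing factor Cdc6 3.21-fold (SE 0.11). Of 59 members 33 fell and 2 rose, against 40 and 3 adjusted over the list alone, with a median of -0.61 (adjusted p = 4.91e-09, adjusted p = 0.324 with an estimated correlation). The 2 that rose, chosen after their values were seen, were the D-type cyclins Ccnd1 (2.53) and Ccnd2 (1.95). Of 53 G2/M and mitosis genes 30 fell and 0 rose, against 36 and 0 adjusted over the list alone, with a median of -0.62 (adjusted p = 2.27e-09, adjusted p = 0.324 with an estimated correlation). The phosphatase gene Cdc25b was 2.61-fold lower (SE 0.13), Cenpk 2.60-fold (SE 0.13), cyclin B1, Ccnb1, 2.26-fold (SE 0.14) and Ttk, undetected after deletion, at least 2.01-fold (adjusted p = 0.0146). These counts rested on both deletion arrays: without deletion replicate 1, 7 G1/S and 2 G2/M genes fell, and without deletion replicate 2, 4 and 3, while the list calls held. Calls were lost without deletion replicate 1 on Ccnb1, Orc1 and Ttk (adjusted p = 0.0558, 0.0785 and 0.0881) and without deletion replicate 2 on Ccne1, Orc1 and Ttk (0.0502, 0.0821 and 0.0717). Without control replicate 1, 2 G2/M genes rose. The erythroid list, whose cells divide rapidly, moved the same way in these arrays with a median of -2.66. Quiescence and cell cycle inhibitor genes did not pass as a list, with 3 of 24 up and 7 down, against 6 and 11 adjusted over the list alone (adjusted p = 0.519), with Cdkn1a up and Rb1 2.47-fold lower (SE 0.11), and 2 fell without control replicate 2, deletion replicate 1 or deletion replicate 2.

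Targets of p53 and regulators of apoptosis moved both ways. Of 33 p53 targets 12 rose and 6 fell, against 13 and 7 adjusted over the list alone, and the list did not pass (median 0.33, or 0.17 with 6 undetected members at their bound, adjusted p = 0.0680). Beside Cdkn1a, Phlda3, undetected in controls, rose at least 4.51-fold (adjusted p = 0.00254). Of 37 apoptosis genes 11 rose and 4 fell, against 13 and 5 adjusted over the list alone (adjusted p = 0.260). The pro-apoptotic BH3-only genes Bmf and Bbc3 moved apart, Bmf 9.15-fold lower (SE 0.12) and Bbc3 3.67-fold higher (SE 0.19). Without control replicate 1 or 2 and deletion replicate 1 or 2, in that order, 7, 8, 5 and 4 p53 targets rose and 4, 3, 1 and 1 fell, and 7, 5, 4 and 3 apoptosis genes rose and 4, 3, 1 and 1 fell. The log2 change of Bbc3 over both of its detected probes was 0.94.

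Lists of nuclear genes for mitochondrial energy metabolism were shifted slightly down as sets, but most members did not pass: 26 of the 188 genes in the 4 lists fell, or 13.8%, against 14.1% of all genes, 3 rose, or 1.6% against 14.8%, and their median log2 change was -0.18 against 0.0019. The share that fell depended on the settings: 27.7% (52 genes) against 16.3% of all genes without background correction, 27.7% against 16.4% with the authors' processed values, 29.3% against 17.1% with an intensity trend and robust prior, 26.1% against 17.6% with median scaling, 21.3% against 15.8% with normexp without control probes, and 8.0% (15 genes) against 1161 of 10519 genes with the replicate block. Meanwhile, in the same arrays the erythroid and B lymphoid lists had medians of -2.66 and -2.24. Of 44 complex I genes 4 fell and 2 rose, against 4 and 1 adjusted over the list alone (median -0.19, adjusted p = 0.0316, adjusted p = 0.324 with an estimated correlation), with Ndufb9 1.68-fold (SE 0.13), Ndufb10 1.68-fold (SE 0.11) and the assembly factor Ndufaf1 1.62-fold lower (SE 0.11). Timmdc1 had a log2 change of -0.87 (adjusted p = 0.300) with deletion arrays at 8.56 and 6.85, or -1.75 without deletion replicate 1 (adjusted p = 0.0255) and -0.02 without deletion replicate 2 (adjusted p = 0.953). The risen genes, chosen after their values were seen, were Ndufb11 (0.84) and Ndufaf4 (0.49). With the replicate block 1 complex I gene rose, and with the mean of all detected probes 0 rose. Of 48 genes of complexes II to V 9 fell and 0 rose, against 6 and 0 adjusted over the list alone (median -0.11, adjusted p = 0.0301, adjusted p = 0.364 with an estimated correlation), with Cox7b 2.04-fold (SE 0.11), Cox11, a copper chaperone of complex IV, 2.00-fold (SE 0.13), Cox7a2 1.78-fold (SE 0.14) and the ATP synthase inhibitor Atpif1 1.64-fold lower (SE 0.13). This list and the 188 genes leave out the complex IV isoform gene Cox6a2, which rose 13.7-fold as given above. Of 27 tricarboxylic acid cycle genes 4 fell and 0 rose, against 1 and 0 adjusted over the list alone (median -0.25, adjusted p = 0.0369, adjusted p = 0.324 with an estimated correlation), with Aco1, the cytosolic iron regulatory protein, 2.14-fold lower (SE 0.15). Pdk2 (log2 change -0.75, adjusted p = 0.0624, detected on 1 deletion array) and Ogdh (-0.63, adjusted p = 0.128) did not pass. Of 72 mitochondrial ribosomal protein genes 9 fell and 1 rose, against 1 and 0 adjusted over the list alone (median -0.17, adjusted p = 0.0112, adjusted p = 0.324 with an estimated correlation). Mrpl49, Mrpl14, Mrpl52 and Mrps18c were 1.87-fold (SE 0.11), 1.64-fold (SE 0.13), 1.63-fold (SE 0.11) and 1.56-fold lower (SE 0.12), and Mrps6, chosen after its value was seen, rose (0.73). Falls in complex I, complexes II to V, the tricarboxylic acid cycle and the mitochondrial ribosome numbered 4, 4, 5 and 5 without control replicate 1, 3, 4, 1 and 4 without control replicate 2, 1, 0, 0 and 0 without deletion replicate 1, and 0 in each without deletion replicate 2. The call on each gene named here as lower was lost without deletion replicate 1 (adjusted p from 0.0525 for Cox11 to 0.111 for Ndufb9) and without deletion replicate 2 (from 0.0559 for Cox7b to 0.145 for Mrps18c). Those on Atpif1 (0.0540) and Mrps18c (0.0510) were lost without control replicate 1, and those on Atpif1 (0.0586) and Mrpl14 (0.0596) without control replicate 2. Leaving out control replicate 1 ended the calls on complex I (adjusted p = 0.0579), complexes II to V (0.102) and the tricarboxylic acid cycle (0.0595), and leaving out deletion replicate 2 did so too (0.0943, 0.0526 and 0.0526). Genes named by the platform table alone, a setting chosen after seeing the data, gave 0.0623 for the tricarboxylic acid cycle, and without deletion replicate 1 it was 0.0754.

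Genes of mitochondrial protein quality control and of autophagy that passed mostly fell. Of 22 mitochondrial chaperone and protease genes 5 fell and 2 rose, against 7 and 2 adjusted over the list alone (median -0.27, adjusted p = 0.0309, adjusted p = 0.324 with an estimated correlation). The inner membrane protease gene Afg3l2 was 2.02-fold (SE 0.11) and the presequence protease gene Pitrm1 1.89-fold lower (SE 0.12), and the transporter Abcb10, undetected after deletion, at least 1.38-fold (adjusted p = 0.0104). Htra2 had a log2 change of -0.84 (adjusted p = 0.0514) and the matrix chaperonin Hspd1 of -0.27 (adjusted p = 0.149), with 1.55 on a dimmer Hspd1 probe (adjusted p = 0.159) and 0.64 for the mean of both (adjusted p = 0.185). The members that rose were Atf5, given above, and, chosen after its value was seen, the matrix chaperone Hspa9 (0.54). Over all detected probes the list gave adjusted p = 0.228, Afg3l2 a log2 change of -0.55 (adjusted p = 0.0587) and Pitrm1 of -0.06 (adjusted p = 0.699), and the list's call was also lost without control replicate 1, deletion replicate 1 or deletion replicate 2 (adjusted p = 0.0532, 0.0503 and 0.0566). Of 49 autophagy and mitophagy genes 11 fell and 0 rose, against 9 and 0 adjusted over the list alone (median -0.22, adjusted p = 0.0356, adjusted p = 0.324 with an estimated correlation). Wipi1 was 2.85-fold (SE 0.16), Atg4b 2.27-fold (SE 0.13), the mitophagy receptor gene Optn 2.22-fold (SE 0.26) and Atg2a 2.08-fold lower (SE 0.19). In the same arrays the erythroid and B lymphoid lists had medians of -2.66 and -2.24, and the megakaryocyte and T and NK lists 1.09 and 0.88. The log2 change of Optn over both of its probes was -0.80 (adjusted p = 0.0786), and its call was also lost with the replicate block (0.0505) and without a detection filter (0.0721), control replicate 1 (0.0669), control replicate 2 (0.118) or deletion replicate 2 (0.113). Without deletion replicate 1 and 2 the calls were lost on Abcb10 (0.0649 and 0.0832), Afg3l2 (0.0580 and 0.0594), Pitrm1 (0.0754 and 0.0731), Atg2a (0.104 and 0.107) and Atg4b (0.0555 and 0.0566). The autophagy call was lost without control replicate 2 (adjusted p = 0.0668), with detection required on all arrays (0.0554) and with platform-table names alone (0.0530). Without control replicate 2, deletion replicate 1 or deletion replicate 2, 5, 2 and 1 autophagy genes and 3, 0 and 0 chaperone and protease genes fell, and 2 autophagy genes rose without control replicate 1. The receptor gene Sqstm1 had a log2 change of 0.19 (adjusted p = 0.307). Phb and Pax5 had no probe that passed the detection filter, and Pink1 was not analysed here.

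**Figure D3:**
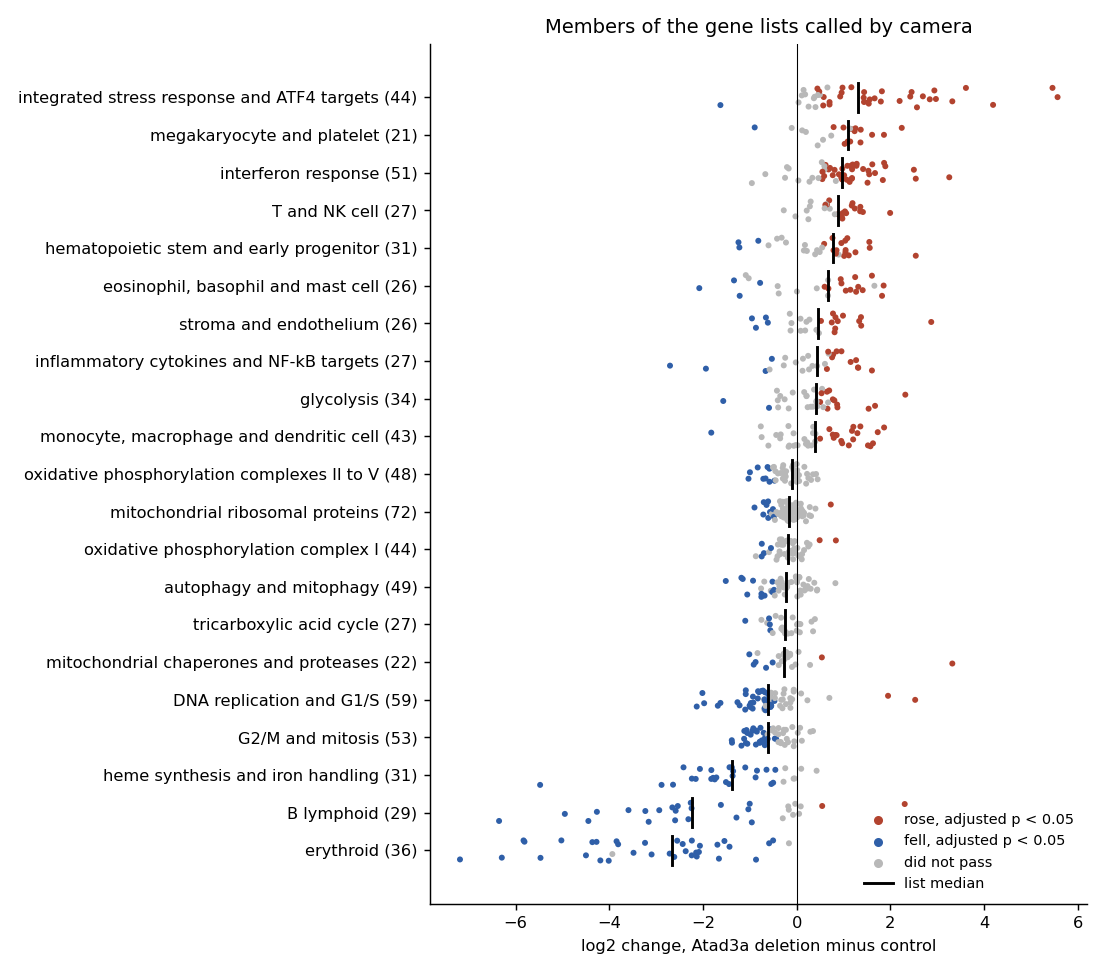
Log2 change between deletion and control (horizontal axis) of each tested member of the 21 gene lists called by camera, 1 list per line with its number of members, ordered by median. Red and blue points rose or fell at an adjusted p under 0.05, grey points did not pass, and black bars are list medians, from 1.30 for the integrated stress response to -2.66 for the erythroid list.

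The glycolysis list was shifted up as a set, but 20 of its 34 members did not pass. Cell type lists moved in the same arrays, with medians of 1.09 for megakaryocyte, 0.88 for T and NK and 0.40 for monocyte genes. Those of the erythroid and B lymphoid lists were -2.66 and -2.24. Vegfa, a hypoxia-inducible growth factor gene and no glycolytic enzyme, rose 4.99-fold (SE 0.17), the phosphofructokinase gene Pfkp 3.19-fold (SE 0.15), the hypoxia regulator gene Hif1a, detected on 1 control array, 2.90-fold (SE 0.34) and Pgam1 1.83-fold (SE 0.11). Of the 34 members 12 rose and 2 fell, against 19 and 2 adjusted over the list alone, with a median of 0.42 (adjusted p = 0.00286, adjusted p = 0.324 with an estimated correlation). The 2 that fell, chosen after their values were seen, were Pfkm (-1.57), a phosphofructokinase isoform, and Pfkfb3 (-0.59). Only 2 members rose and 1 fell without deletion replicate 1 or deletion replicate 2, and the calls on Hif1a (adjusted p = 0.143 and 0.120) and Pgam1 (0.0714 and 0.0731) were lost. That on Hif1a was also lost without a detection filter (0.0738), and its rise was 2.58-fold with each control array at its floor or above.

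Further lists did not pass, though single members changed. Of 36 genes of mitochondrial dynamics and membrane structure 9 fell and 1 rose, against 10 and 1 adjusted over the list alone (adjusted p = 0.120), and beside Atad3a itself Chchd10 was 3.50-fold lower (SE 0.15). Of 36 genes of mitochondrial DNA maintenance and expression 6 fell and 0 rose, against 2 and 0 adjusted over the list alone (adjusted p = 0.106), with the DNA polymerase gene Polg 2.21-fold (SE 0.20) and Mterf2 1.83-fold lower (SE 0.12). Tfam had a log2 change of -0.12 (adjusted p = 0.502). Of 33 mitochondrial import genes 2 rose and 2 fell, against 1 and 1 adjusted over the list alone (adjusted p = 0.269), with Immp2l 1.66-fold higher (SE 0.12). Of 36 antioxidant and NRF2 target genes 8 fell and 2 rose, both over all probes and adjusted over the list alone (adjusted p = 0.120), with the mitochondrial thioredoxin reductase gene Txnrd2 3.88-fold (SE 0.12) and Gclm 3.77-fold lower (SE 0.12). Of 29 fatty acid oxidation genes 2 rose and 3 fell, against 1 and 3 adjusted over the list alone (adjusted p = 0.786), with Crat lower (log2 change -2.07, SE 0.20) and the carnitine carrier gene Slc25a20 1.63-fold higher (SE 0.12). Of 61 cytosolic ribosomal protein genes 4 rose and 2 fell, against 0 and 1 adjusted over the list alone (adjusted p = 0.0778), with Rpl22 1.68-fold higher (SE 0.12) and Rpl3l 2.86-fold lower (SE 0.16). Of 34 proteasome genes 3 rose and 3 fell, against 3 and 2 adjusted over the list alone (adjusted p = 0.603), with Psmb1 and the interferon-inducible Psmb8 2.38-fold (SE 0.12) and 2.42-fold higher (SE 0.14). Of 30 cholesterol synthesis genes 1 rose and 1 fell, against 1 and 0 adjusted over the list alone (adjusted p = 0.786), with Npc1 2.01-fold higher (SE 0.11), though a dimmer Npc1 probe fell (-0.60), and Pmvk 1.59-fold lower (SE 0.14). Of 23 immediate early and heat shock genes 4 rose and 5 fell, against 4 and 6 adjusted over the list alone (adjusted p = 0.820), with Ier3 2.27-fold higher (SE 0.13). At most 3 members of any of these lists rose or fell without deletion replicate 1 or 2. The calls on Immp2l, Mterf2, Polg, Npc1, Pmvk, Psmb8, Rpl22 and Slc25a20 were lost without either (adjusted p from 0.0515 to 0.156), that on Ier3 without the former (0.0532) and that on Psmb1 without the latter (0.0504). Without control replicate 1, 3 mitochondrial DNA and 5 antioxidant genes and 1 ribosomal gene fell, 1 import gene and 0 dynamics genes rose, 4 cholesterol genes rose, and the call on Pmvk was lost (adjusted p = 0.0561). Without control replicate 2, 4 dynamics, 2 mitochondrial DNA, 5 antioxidant, 0 import, 1 ribosomal and 2 immediate early genes fell, 0 dynamics, 0 ribosomal, 1 import and 1 antioxidant genes rose, and the call on Rpl22 was lost (0.0504). Median scaling ended the call on Slc25a20 (0.0569). The sex-linked list had too few detected members for a test. Every Xist probe was detected on all 4 arrays, as was 1 of the Ddx3y probes. Of the Uty probes, 1 was detected on 1 control array and on both deletion arrays. The other Ddx3y and Uty probes, and every probe of the Y-linked genes Eif2s3y, Kdm5d, Usp9y, Zfy1 and Zfy2, were undetected on all 4 arrays.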

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

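Naming by the platform table alone was chosen after seeing the data; the other settings were planned. No result reversed its direction where it was called. Genes higher and lower numbered 561 and 621 with at least a 2-fold change required, by construction of that threshold, and 278 to 1311 and 419 to 1359 with 1 array left out, where fewer samples are tested and the lone sample is assumed to vary like the other group. In these fits the log2 change of Atad3a lay between -1.14 and -0.98. Median scaling gave 1223 higher and 1854 lower genes. With an estimated correlation, which leaves few degrees of freedom, adjusted p rose to 0.324 for the stem, erythroid, heme, megakaryocyte, B lymphoid, monocyte, stroma, complex I, mitochondrial ribosome, tricarboxylic acid, autophagy, mitochondrial chaperone, integrated stress, interferon, G1/S, G2/M, glycolysis and NF-kB lists, to 0.353 for T and NK and for eosinophil, basophil and mast cells, and to 0.364 for complexes II to V. Detection at p under 0.01 on all arrays gave 0.0823 for stroma and 0.0554 for autophagy. The mean of all detected probes gave 0.228 for mitochondrial chaperones and 0.0585 for NF-kB. Platform-table names alone gave 0.0623 for tricarboxylic acid, 0.0530 for autophagy and 0.0551 for NF-kB. With 1 array left out, adjusted p ran from 0.0275 to 0.0583 for eosinophil, basophil and mast cells, 0.0272 to 0.0943 for complex I, 0.00914 to 0.102 for complexes II to V, 0.0284 to 0.0754 for tricarboxylic acid, 0.0291 to 0.0668 for autophagy, 0.0272 to 0.0566 for mitochondrial chaperones and 0.0232 to 0.0762 for NF-kB. For calls that ended under other filters, names or probes the cause was not tested. The other 14 called lists were called without each single array.

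Whether same-numbered samples share a litter, day or slide is not given in the sources used here. Deviations of same-numbered arrays correlated at 0.025 across probes, which shows no strong shared effect but cannot exclude pairing. With the replicate block 1264 genes were higher and 1161 lower, Atad3a kept its log2 change of -1.07 (adjusted p = 0.0195), and 21 lists were called. Over all settings, 1707 values of named genes stayed on their side of the threshold, 134 calls were lost and 16 gained. Of 126 named genes other than Atad3a, 45 were lost without deletion replicate 2, 42 without deletion replicate 1, 16 without control replicate 2 and 11 without control replicate 1. Without background correction 45 of 126 moved by over 1.5-fold, with the authors' processed values 44 and with normexp without control probes 31, each towards a smaller change, since signal over background sets the size of a change for dim probes. Lists that were not called stayed so in 228 values and were called in 10. No slide block could be run.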

Other observations

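The 10 lists named in the paragraphs that follow were chosen after the main results were seen. Neither they nor the immunoglobulin probes below were tested with single arrays left out or with other processing. Serine and one-carbon metabolism genes rose together: 8 of 12 rose and 1 fell, with a median log2 change of 1.42 (camera adjusted p = 0.00213 over the lists added, adjusted p = 0.480 with an estimated correlation). Beside Aldh1l2, the amino acid transporter gene Slc1a4 rose by a log2 change of 2.45 (SE 0.16), Phgdh, which starts serine synthesis, by 2.43 (SE 0.43), and the mitochondrial folate enzyme genes Mthfd2 by 1.56 (SE 0.16) and Shmt2 by 1.44 (SE 0.16). The cytosolic counterpart Mthfd1 fell (-1.27, SE 0.15), while cytosolic Shmt1 rose (1.40, SE 0.13). Of 12 genes 5 also stand in the integrated stress response list. Cytosolic aminoacyl-tRNA synthetases did not pass as a list, with 6 up and 1 down of 19 (median 0.25, adjusted p = 0.0553), and mitochondrial ones, 1 up and 1 down of 14, had a median of -0.11 (adjusted p = 0.535).

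Early B cell genes and antibody genes moved apart. Of 14 genes of the pre-B receptor and recombination 10 fell and 1 rose (median -2.42, adjusted p = 5.36e-06, adjusted p = 0.381 with an estimated correlation), the gene that rose being Dntt. The interleukin 7 receptor gene Il7r had a log2 change of -0.18 (adjusted p = 0.384). Of 13 mature B cell genes 4 rose and 5 fell (adjusted p = 0.804), and those that rose were Ccr6 (1.81) and the antigen presentation genes Ciita (1.47), Cd74 (0.97) and H2-Oa (0.89), which dendritic cells also express. Yet of 62 detected probes that the array's own names assign to immunoglobulin segments, 31 rose and 0 fell, with a median log2 change of 1.22. The control arrays differed here too, with medians of 0.233 on replicate 1 and -0.233 on replicate 2 relative to the control mean. Heavy chain probes rose in 22 of 37 cases and light chain probes in 9 of 25.

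The dilution test was chosen after the result was seen, and the prediction for the endoplasmic reticulum was written before its list was tested. Loss of erythroid and B cells could raise the transcripts of all remaining cells alike, but above a 4-fold rise lay 13 of 44 integrated stress response members and 2 of 191 stem, megakaryocyte, T and NK, neutrophil, monocyte and basophil markers (two-sided Fisher's exact test across genes, which are not independent replicates, p = 5.405e-09), 3 of 217 with stroma and endothelium markers added (p = 6.488e-09), and 6 of 44 against 1 of 191 both without background correction and with the authors' processed values (p = 0.0001932), which argues against dilution as the only source. The medians decide nothing, with 1.30 for the list and 1.09 for the highest marker list but 0.70 and 1.09 with detection at p under 0.01 on all arrays, a filter that leaves out members undetected in controls, so dilution of the smaller rises was not excluded. Stress of the endoplasmic reticulum as the only trigger would raise its chaperones too, and these had a median of 0.4374, or 0.41 with 1 member at its bound, with 8 of 26 up and 1 down (adjusted p = 0.00133, adjusted p = 0.609 with an estimated correlation), between what that trigger and another would give, with Hspa5, dim on these arrays, at -0.01. A trigger in the mitochondria, where the deleted gene acts, is a hypothesis that these arrays did not test.

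The comparison with B lineage markers was chosen after the result was seen, and the prediction for plasma cells was written before their list was tested. The rise of immunoglobulin probes could come from more B lineage cells. The B lymphoid markers, which include early B cell genes such as Rag1 and Vpreb3, had a median of -2.244, or -0.93 with the authors' processed values. Their fall was part of the pattern to be explained, and it argues only against more early B cells. The mature B cell list had a median of -0.08 (camera adjusted p = 0.804), so it cannot decide whether later B lineage cells were more frequent. More plasma cells would raise plasma cell genes together: the 14 that are not stress response genes had a median of 0.08282 without passing (adjusted p = 0.810), 3 up and 3 down, with -0.10 on deletion replicate 1 and 0.37 on deletion replicate 2, among them Tnfrsf17 (1.59) and Sdc1 (-1.46). The full plasma cell list, 5 up and 3 down of 18, did not pass either (adjusted p = 0.291), which leaves plasma cells open, the more so as 49 of the 62 immunoglobulin probes were also higher on deletion replicate 2 than on deletion replicate 1 (medians 1.72 and 1.03). Variable segments resemble each other, so cross-hybridisation may add to the rise and was not tested. Probes not named for a variable segment, given after their values were seen, differed. Those named IGHG (3.22 and 2.21) and IGHA (2.34) rose. Those named IGHG1 (1.41), IGH-4 (1.23), IGH-6 (0.68 and 0.43), IGK-C (0.30) and IGLC2 (-0.73) did not pass.

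The test of leftover erythroid cells was chosen after the result was seen. The fall of erythroid genes could reflect fewer erythroid progenitors, or fewer mature erythroid cells left behind by lineage depletion in the deletion samples than in the controls. Red cell membrane and hemoglobin genes had a median of -3.709 with 17 of 20 down (adjusted p = 9.81e-12, adjusted p = 0.480 with an estimated correlation). The globin genes Hba-a1 (-3.94, SE 1.38), Hbb-bs (-3.21, SE 1.18) and Hbb-bt (-2.97, SE 1.18) did not pass. The dim globin gene Hbb-b2, undetected after deletion, did fall (adjusted p = 0.00176). Erythroid regulators and receptors, which act before the TER-119 antigen appears, had a median of -1.409, or -0.86 with Sox6 at its bound, with 8 of 15 down (adjusted p = 0.000329, adjusted p = 0.480 with an estimated correlation), among them Epor (-3.10), Tal1 (-2.24), Myb (-1.44) and Sox6 (undetected after deletion, at least 1.82-fold), while Nfe2 (-0.16), Ldb1 (0.09) and Cbfa2t3 (0.09) did not pass. Mature erythroblasts carry most regulators too, so the 2 sources cannot be told apart here.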
